A study of Mus musculus with 12 samples.

How the data were processed

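Polyadenylated RNA was sequenced from 12 cultures of mouse embryonic stem cells of the male line E14 Tg2a. Per the labels, 3 independent Pcbp1 knockout clones (KO) and 3 independent control clones (Scr in the series text, wild type or WT in the sample labels) were each grown in 2 culture conditions. The naive condition was serum-free medium with LIF and inhibitors of MEK and GSK3. The epiblast-like cell (EpiLC) condition was 48 h with bFGF, activin A and serum replacement on fibronectin. This gave 4 groups of 3 libraries each: naive WT, naive KO, EpiLC WT and EpiLC KO. Libraries are named by group and the replicate number in the labels.

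The deposited table holds raw read counts per gene, with no normalization. Per the file headers, the authors made it with featureCounts 2.0.1 on the GENCODE vM25 annotation, and the labels name fastp, FastQC, STAR and DESeq2 without versions and the mouse build GRCm38/mm10. The header shows no option for strand, read pairs, multi-mapping reads or reads that overlap several genes. Under the tool's defaults, reads were therefore counted without regard to strand, although the library kit keeps strand, and reads shared between paralogs or overlapping genes were not counted. Counts of paralog families (Magea, Nat8f, Usp17l, ribosomal proteins) and of genes that overlap a neighbour carry that limit. The other deposited column, the summed exon length of each gene in bp per the file headers, was not used. Every column of counts was used. The table lists 55487 genes, of which 55141 have a symbol. The 346 genes without a symbol took under 0.0313% of the counts of every library.

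Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3) and are given as CPM, the scaled count of edgeR, with mean, SD and n = 3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total count 15), which left 18134 genes. All 12 libraries entered a single edgeR quasi-likelihood fit with 8 residual degrees of freedom, and 5 contrasts were tested: KO against WT in naive cells, KO against WT in EpiLCs, EpiLC against naive in WT, EpiLC against naive in KO, and the interaction between genotype and condition. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. A log2 fold change is given with a standard error, taken as its size divided by the square root of its F statistic. Every adjusted p of a gene is from this edgeR fit.

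The 37 gene lists were fixed before the data were examined, as were the contrasts, the tests, most alternative settings and the rule for naming genes. They cover naive, core, and formative and primed pluripotency, and DNA methylation enzymes. For metabolism they cover serine, glycine and one-carbon metabolism; 4 further groups of amino acid enzymes; amino acid transporters; ATF4 targets; cytosolic aminoacyl-tRNA synthetases; mTORC1 and lysosome; glycolysis; nuclear and mitochondrially encoded oxidative phosphorylation; cholesterol biosynthesis; and iron homeostasis. The others are the PCBP family; responses to ERK, WNT, NODAL and activin, and LIF and STAT3; p53 targets; S phase; G2 and M phase; ribosomal proteins; markers of primitive streak and mesoderm, endoderm, trophoblast, neuroectoderm, 2-cell-like cells, and fibroblasts and feeders; germline genes; imprinted genes; Y-linked genes; and RNA quality and stress. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the 37 lists within each contrast. Each was also tested with an estimated correlation and with fry, which does not compare a list with other genes. Counts of called members are given over all genes and adjusted over the list alone.

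Named genes were Pcbp1 and its relatives; for each KO against WT contrast the 8 called genes with the highest and the 8 with the lowest log2 fold change, for EpiLC against naive in WT the 5 highest and 5 lowest, and for the interaction the 6 highest and 6 lowest; up to 4 members of each described list with the smallest adjusted p; and any member of the naive and the formative lists. Genes named for their fold change needed a mean of at least 5 CPM over the libraries compared, a gene name other than a clone or predicted-gene identifier, and, except for the interaction, groups that did not overlap. Some genes that this rule names are not reported here. A transition score per library was the mean log2 CPM of the formative and primed list minus that of the naive list, compared by a 2-sided exact permutation test, for which 3 against 3 libraries allow a smallest p of 0.1. The share of the WT transition seen in KO was the median ratio of the log2 fold changes, with a 95% bootstrap interval over genes (2000 draws). Chromosomes were tested as sets with camera.

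Whether a replicate number marks the same clone was tested by correlating the libraries' deviations from their group mean across genes. Naive and EpiLC libraries of the same genotype and number correlated at 0.299 to 0.377 in WT and 0.243 to 0.387 in KO, above every pair of unlike numbers (at most -0.0528 and 0.127), and in each genotype 6 of 6 libraries matched their own number best. A block by clone was therefore an alternative for the EpiLC against naive contrasts and the interaction. The main fit had no such block and treats the libraries of a clone as independent. Equal numbers did not pair WT with KO libraries (-0.0811 to 0.0556 in naive cells, -0.361 to -0.178 in EpiLCs). Unlike numbers of WT and KO correlated at -0.109 to 0.0996 in naive cells and at -0.133 to 0.449 in EpiLCs. The 0.449, between EpiLC KO replicate 1 and EpiLC WT replicate 3, exceeds every value within a clone, although these libraries share no clone. A correlation of this size therefore does not by itself mark a clone, and its source was not tested. Each library was checked against the other libraries of its group for duplicated counts, and none was found.

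Alternative settings were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, other filters and thresholds, a block by replicate number, the compared libraries alone and the omission of each library in turn. A removal of each library's trend of counts on transcript GC content was added after seeing the data, as was a test of the lists with both an estimated correlation and EpiLC WT replicate 2 omitted. GC content came from the GENCODE vM21 transcripts, the longest of each gene, and was known for 18111 of the genes tested. Tested on simulated data with 200 changed genes among 18134, the edgeR fit recovered 46.3% of 2-fold and 81.8% of 4-fold changes in the naive KO against WT contrast, with 4.04% false calls. It recovered 47.8% and 68.2% in the EpiLC contrast, with 3.41% false calls, and 17.9% and 57.6% for the interaction, with 5.56% false calls. The DESeq2 test made 22.6% and 24.4% false calls in the KO against WT contrasts. A shifted list was called in each of these contrasts, and 0 of the others. The simulated genes varied independently of each other, so this does not test the calls of lists whose genes vary together. The simulated libraries were also drawn independently, with no differences between clones. A count of 3 in a library, the limit that a count of 0 allows, came to 0.0689 to 0.112 CPM. Such limits cover counting error only.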

Results

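RNA was sequenced from Pcbp1 knockout (KO) and control (WT) clones of a mouse embryonic stem cell line, in naive culture and after 48 h in the medium that yields epiblast-like cells (EpiLCs), an in vitro counterpart of the early postimplantation epiblast. Each of the 4 groups (naive WT, naive KO, EpiLC WT and EpiLC KO) held 3 libraries, 1 per clone. The total counts of replicates 1, 2 and 3 were 32274141, 31330742 and 38269109 in naive WT and 33124870, 35230853 and 32274451 in naive KO. They were 39456442, 27146744 and 30608961 in EpiLC WT and 42204511, 36378152 and 34717620 in EpiLC KO. The first principal component, with 72% of the variance, separated naive cells from EpiLCs, and the second, with 11%, separated KO from WT. The series asks how the RNA-binding protein PCBP1 acts in the transition from naive to primed pluripotency and in amino acid metabolism.

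Pcbp1 (ENSMUSG00000051695.6, GRCm38 chromosome 6, 86524492 to 86526321), the targeted gene, was lower in every KO library than in every WT library of its condition. In naive cells the WT libraries gave 475.4, 417.9 and 474 CPM and the KO libraries 295.3, 302.5 and 302.9 CPM. In EpiLCs the WT libraries gave 692.1, 511.9 and 591.5 CPM and the KO libraries 250.3, 301.8 and 264.9 CPM. Pcbp1 fell by 0.60 ± 0.111 on the log2 scale (SE, n = 3 per group, edgeR adjusted p = 0.00599) in naive cells and by 1.14 ± 0.112 (adjusted p = 0.000137) in EpiLCs. The difference between these effects did not pass (interaction -0.53, adjusted p = 0.18). Transcript levels alone do not show the amount of protein, and the labels give no position for the edit. Of its relatives, Pcbp4 fell in naive cells (-0.49 ± 0.115, adjusted p = 0.0199) and in EpiLCs (-0.39 ± 0.114, adjusted p = 0.0394). The naive call of Pcbp4 ended without naive KO replicate 1 (adjusted p = 0.0803) or naive WT replicate 3 (0.0557), and its EpiLC call ended without any library but EpiLC WT replicate 2 (adjusted p of 0.139, 0.0775, 0.0752, 0.122 and 0.075). Pcbp2, Pcbp3 and Hnrnpk did not pass in either condition, with adjusted p of 0.85, 0.255 and 0.505 in naive cells and 0.453, 0.533 and 0.404 in EpiLCs.

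**Figure D1:**
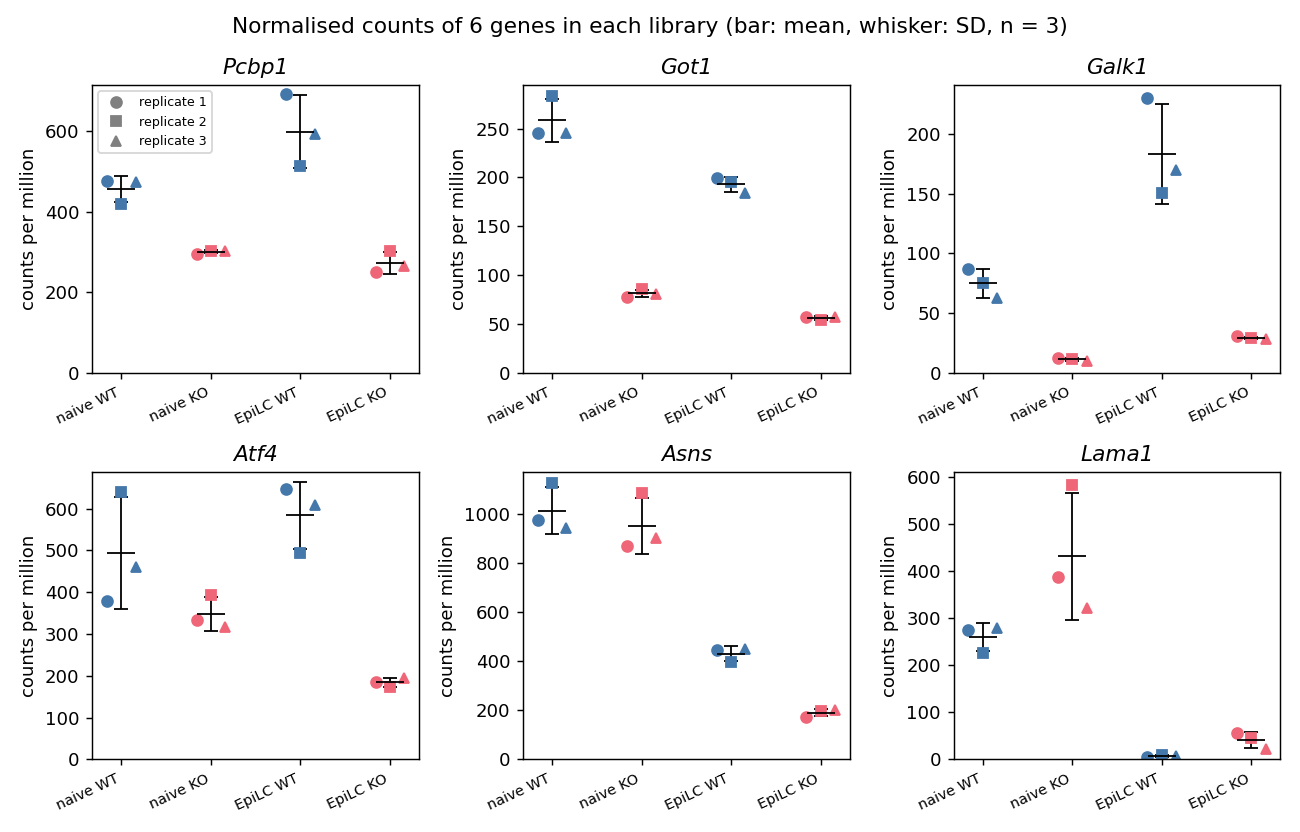
CPM (vertical axes, from 0) of 6 genes in each of the 12 libraries, in 4 groups along the horizontal axes. Bars show the mean and whiskers the SD (n = 3). Pcbp1, Got1 and Galk1 lie lower in every KO library than in every WT library of the same condition, Atf4 and Asns differ in EpiLCs, and Lama1 is higher in KO EpiLCs (mean 41.0 CPM) than in WT EpiLCs (6.88 CPM).

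The first comparison asked what loss of Pcbp1 changes in naive cells. Of the genes with the largest falls, Calb2, which encodes the calcium-binding protein calretinin, went from 22.8 ± 8.60 CPM in naive WT to 1.18 ± 0.394 CPM in naive KO (SD, n = 3), a log2 change of -4.27 ± 0.384. Actn3, an alpha-actinin gene (-3.52 ± 0.27), Gprc5c (-3.07 ± 0.563) and Nphs1, which encodes nephrin (-2.86 ± 0.369), also fell. So did Lefty1 (-3.28 ± 0.603) and Lefty2 (-3.07 ± 0.503), which encode NODAL antagonists. Adgrg1, an adhesion receptor gene, fell by 3.14 ± 0.629, a call that ended without naive KO replicate 1 (adjusted p = 0.0501). The genes with the highest fold changes included Nat8f7 (5.42 ± 0.675) and Nat8f3 (4.25 ± 0.623), of the N-acetyltransferase 8 family. The others were the X-linked genes Magea2 (4.37 ± 0.605), Magea8 (3.95 ± 0.572) and Magea6 (3.80 ± 0.822) of a family usually limited to the germline, and Akr1c18 (4.22 ± 0.441), Pet2 (3.69 ± 0.468) and Folh1 (3.61 ± 0.335). The Nat8f and Magea genes are paralogs with shared sequence, Magea2 overlaps Magea5, and the mean of each of these 8 genes in naive WT was under 3 CPM. The call of Magea6 ended without naive WT replicate 3 (adjusted p = 0.0634).

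Got1 (chromosome 19, 43499752 to 43524605), the cytosolic aspartate aminotransferase, fell by 1.67 ± 0.0873 (258.3 ± 21.6 to 81.31 ± 3.78 CPM, SD, n = 3, edgeR adjusted p = 2.08e-06). It was 1 of 2 genes to fall in the list of 25 for proline, arginine, glutamine, glutamate and aspartate, and the list did not pass (camera adjusted p = 0.0854). Of 20 genes of serine, glycine and one-carbon metabolism, 5 fell and 0 rose, also 5 adjusted over the list alone (camera adjusted p = 0.00373; adjusted p = 0.33 with an estimated correlation). Gldc, of the mitochondrial glycine cleavage system, fell by 1.62 ± 0.135 (adjusted p = 7.01e-05). Phgdh, the first enzyme of serine synthesis (-1.17 ± 0.307), and Shmt2, the mitochondrial serine hydroxymethyltransferase (-0.81 ± 0.208), also fell. The call of Phgdh ended without naive KO replicate 1, naive WT replicate 2 or naive WT replicate 3 (adjusted p of 0.101, 0.0949 and 0.0657), and that of Shmt2 without naive KO replicate 1, naive KO replicate 3, naive WT replicate 2 or naive WT replicate 3 (0.0995, 0.0655, 0.0812 and 0.0576).

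Of 23 cholesterol biosynthesis genes, 6 fell in naive KO and 11 adjusted over the list alone, with 0 rising (camera adjusted p = 0.000225; adjusted p = 0.394 with an estimated correlation). They included Fdps, the farnesyl diphosphate synthase (-0.68 ± 0.149), whose call ended without naive KO replicate 1 (adjusted p = 0.0569). Of 10 genes of the NODAL and activin response, 4 fell and 5 adjusted over the list alone (camera adjusted p = 0.000276; adjusted p = 0.394 with an estimated correlation). They were Lefty1, Lefty2, Foxh1, a SMAD cofactor (-1.14 ± 0.14), and Pmepa1 (-1.22 ± 0.308), whose call ended without any naive library but KO replicate 3 (adjusted p from 0.0503 to 0.0887). Of 17 p53 targets, 4 rose and 6 adjusted over the list alone, with 0 falling (camera adjusted p = 0.00118; adjusted p = 0.474 with an estimated correlation). Bbc3, which encodes the pro-apoptotic protein PUMA, rose by 1.05 ± 0.153, and Mdm2, the p53 ubiquitin ligase, by 0.46 ± 0.0933. The call of Mdm2 ended without naive KO replicate 1 (adjusted p = 0.0612) or naive WT replicate 1 (0.0597). Of 16 S phase genes, 2 fell and 4 adjusted over the list alone (camera adjusted p = 0.00105; adjusted p = 0.474 with an estimated correlation), among them Ccne1, which encodes cyclin E1 (-0.53 ± 0.0834). Of 16 G2 and M phase genes, 2 fell, Aurka (-0.52 ± 0.104) and Aurkb (-0.40 ± 0.0957), and 3 adjusted over the list alone (camera adjusted p = 0.0255; adjusted p = 0.474 with an estimated correlation). That list's call ended without naive WT replicate 1 (0.0734) or naive KO replicate 1 (0.0695), and that of Aurkb without naive KO replicate 1 (0.0821).

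Of 15 naive pluripotency genes, 0 rose or fell (camera adjusted p = 0.919), with log2 fold changes from -0.23 to 0.19. Of 8 core pluripotency genes, 0 passed (camera adjusted p = 0.919). Of 20 formative and primed genes, 3 rose and 0 fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.401). The log2 fold changes of this list went both ways, from -1.84 to 1.03 (adjusted p = 7.62e-06 by fry for a mixed change). The 3 genes that rose were Grhl2 (1.03 ± 0.228), Etv1 (0.74 ± 0.208) and Zic2 (0.52 ± 0.148). Cdh2, a cadherin gene (-1.84 ± 0.641, adjusted p = 0.0947), and Otx2, a homeobox factor (-1.06 ± 0.371, adjusted p = 0.0966), had the lowest fold changes and did not pass over all genes, while Otx2 passed without naive WT replicate 1 (-1.41, adjusted p = 0.027). The calls of Etv1 and Zic2 ended without any 1 of the 6 naive libraries (adjusted p from 0.0565 to 0.156 and from 0.0836 to 0.179), and that of Grhl2 without naive KO replicate 1 (adjusted p = 0.0785), naive WT replicate 1 (0.0515) or naive WT replicate 3 (0.0707). Zic2 lies in a segment of chromosome 14 that was higher in KO clones 1 and 2.

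Across all 18134 genes tested, 1673 differed between naive KO and naive WT (775 rose and 898 fell), 1049 of them by at least 2-fold (552 rose and 497 fell). The count was 1115 without naive WT replicate 1, 850 without naive WT replicate 3 and 678 without naive KO replicate 1. Across genes, which are not independent replicates, the log2 fold change correlated with transcript GC content (Spearman -0.231), and the genes that fell had a higher median GC content (53.8%) than those that rose (46.8%). With the GC trend of each library removed, an alternative chosen after seeing the data, 1793 genes passed, including 1441 of the 1673 (86.1%).

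The second comparison asked what loss of Pcbp1 changes in EpiLCs. Got1 fell by 1.79 ± 0.0878 (192.7 ± 8.13 to 55.7 ± 1.80 CPM, SD, n = 3, edgeR adjusted p = 9.27e-07), and Galk1 (chromosome 11, 116008457 to 116012719), the galactokinase, by 2.65 ± 0.17 (183.4 ± 41.7 to 29.23 ± 1.04 CPM, adjusted p = 6.16e-06). Among the lowest fold changes were also Fut1, a fucosyltransferase gene (-3.81 ± 0.478), Nupr1, a stress-induced transcription regulator (63.2 ± 7.14 to 6.27 ± 0.899 CPM), Chac1, which degrades glutathione (86.1 ± 33.9 to 9.00 ± 0.707 CPM), Mef2b (-2.84 ± 0.493), which overlaps Borcs8, and Nt5dc2 (-2.46 ± 0.264). Ubap1l (-2.86 ± 0.666) and Serpinf1 (-2.59 ± 0.607) fell, with calls that ended without EpiLC KO replicate 1 (adjusted p of 0.0641 and 0.0591) or EpiLC KO replicate 2 (0.0532 and 0.0547), and for Serpinf1 also without EpiLC WT replicate 1 (0.0528). Of the 8 highest fold changes, 7 belonged to the Magea family on the X chromosome: Magea3 (6.14 ± 0.719), Magea8 (5.37 ± 0.629), Magea2 (5.35 ± 0.643), Magea6 (4.65 ± 0.88), Magea5 (4.41 ± 0.533), Magea10 (4.33 ± 0.45) and Magea4 (3.27 ± 0.187, 4.29 ± 0.985 to 41.6 ± 3.68 CPM). The remaining gene, Tktl2, related to transketolase, rose by 3.71 ± 0.343. Reads shared by Magea paralogs were not counted, and several of these genes lay under 1 CPM in EpiLC WT.

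Genes induced through ATF4, the transcription factor of the amino acid and integrated stress responses, were lower in EpiLC KO than in EpiLC WT. Of 26 genes, 18 fell and 0 rose, and 22 fell adjusted over the list alone (median -1.41, camera adjusted p = 1.84e-11; adjusted p = 0.356 with an estimated correlation). Atf4 itself fell by 1.67 ± 0.172 (584.1 ± 79.9 to 184.2 ± 10.9 CPM) and Asns, the asparagine synthetase, by 1.18 ± 0.109 (429.9 ± 30.1 to 190.1 ± 14.9 CPM), beside Nupr1 and Chac1. Of the 26 genes, 11 also stand in another list. In naive cells 1 of 26 fell, and 0 adjusted over the list alone (camera adjusted p = 0.0825). The naive libraries varied within each genotype: the mean log2 CPM of the list was 4.756, 6.087 and 5.305 in WT replicates 1, 2 and 3, and 4.606 to 5.496 in KO. The interaction of the list passed (median -1.02, camera adjusted p = 3.4e-09, and adjusted p = 0.461 with an estimated correlation).

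Of 20 genes of serine, glycine and one-carbon metabolism, 11 fell and 0 rose in EpiLC KO, also 11 adjusted over the list alone (camera adjusted p = 3.11e-06; adjusted p = 0.0393 with an estimated correlation). This was the only 1 of the 19 lists called in this comparison that held with an estimated correlation, and it did not hold so without EpiLC WT replicate 2 (adjusted p = 0.174, a test chosen after seeing the data). Gldc fell by 1.29 ± 0.134, Shmt2 by 1.53 ± 0.211, Psat1, the phosphoserine aminotransferase, by 1.42 ± 0.247 and Amt, another part of the glycine cleavage system, by 0.81 ± 0.109. Of 20 cytosolic aminoacyl-tRNA synthetases, 12 fell and 14 adjusted over the list alone, with 0 rising (camera adjusted p = 1.05e-06; adjusted p = 0.309 with an estimated correlation), among them Sars (-1.30 ± 0.196), Aars (-1.04 ± 0.161), Yars (-0.94 ± 0.155), which overlaps another gene, and Qars (-0.54 ± 0.105). Of 25 genes for proline, arginine, glutamine, glutamate and aspartate, 7 fell and 8 adjusted over the list alone (camera adjusted p = 0.00056; adjusted p = 0.194 with an estimated correlation), including Aldh18a1, of proline synthesis (-1.47 ± 0.262), and the aminotransferase Gpt2 (-1.82 ± 0.327). Of 35 amino acid transporters, 11 fell and 12 adjusted over the list alone (camera adjusted p = 0.0255; adjusted p = 0.388 with an estimated correlation), including Slc1a5 (-1.24 ± 0.193) and Slc7a3 (-0.53 ± 0.114).

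Of 23 genes for threonine, lysine and branched-chain amino acids, 7 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0345; adjusted p = 0.418 with an estimated correlation). Bckdk, the branched-chain ketoacid dehydrogenase kinase (-0.53 ± 0.0793), and Bcat1, a branched-chain aminotransferase (-0.84 ± 0.129), fell, and Aass, of lysine breakdown, rose by 1.78 ± 0.349. This list lost its call without EpiLC WT replicate 2 (adjusted p = 0.235), EpiLC KO replicate 1 (0.0693) or EpiLC KO replicate 3 (0.0542). Of 22 genes for methionine, cysteine and glutathione, 3 fell, Chac1, Csad of taurine synthesis (-1.41 ± 0.245) and Cth of cysteine synthesis (-1.08 ± 0.289), and 5 adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.309 with an estimated correlation). That call ended without EpiLC WT replicate 2 (0.126) or EpiLC KO replicate 2 (0.057). The call of Cth itself ended without EpiLC WT replicate 2 (0.0744) or any 1 of the EpiLC KO libraries (0.0602, 0.0782 and 0.0801).

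Of 22 glycolysis genes, 9 fell and 0 rose in EpiLC KO, and 16 fell adjusted over the list alone (camera adjusted p = 1.05e-06; adjusted p = 0.287 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell by 1.57 ± 0.16, Hk1 and Hk2, which encode hexokinases, by 1.01 ± 0.131 and 0.53 ± 0.0997, and Aldoa, an aldolase, by 0.63 ± 0.121. Of 86 nuclear genes of oxidative phosphorylation, 10 fell and 1 rose, and 4 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.000629; adjusted p = 0.548 with an estimated correlation), for example Uqcrc1 (-0.55 ± 0.104). This call ended without EpiLC KO replicate 1 (0.0583). Of 82 ribosomal protein genes, 7 fell and 2 adjusted over the list alone (median -0.18, camera adjusted p = 1.81e-05; adjusted p = 0.548 with an estimated correlation), for example Rpl13a (-0.57 ± 0.0859). Of 23 cholesterol biosynthesis genes, 4 fell, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.418 with an estimated correlation), a call that ended without EpiLC KO replicate 3 (0.071). Of 16 S phase genes, 5 fell and 6 adjusted over the list alone (camera adjusted p = 0.00899; adjusted p = 0.528 with an estimated correlation), for example Slbp, the histone stem-loop binding protein (-0.35 ± 0.0823), whose own call ended without EpiLC KO replicate 3 (0.0534).

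Markers of primitive and definitive endoderm were higher in EpiLC KO than in EpiLC WT. Of 16 genes, 9 rose and 0 fell, and 10 rose adjusted over the list alone (median 2.36, camera adjusted p = 1.92e-07; adjusted p = 0.196 with an estimated correlation). Cubn, an endocytic receptor gene of visceral endoderm, rose by 2.85 ± 0.389 (1.85 ± 1.28 to 13.2 ± 1.71 CPM), Lama1, a laminin chain, by 2.59 ± 0.36 (6.88 ± 2.58 to 41.0 ± 17.8 CPM), Afp, alpha-fetoprotein, by 4.12 ± 0.638 (0.114 ± 0.0341 to 2.09 ± 0.496 CPM) and Foxa2, an endoderm transcription factor, by 2.78 ± 0.48 (0.112 ± 0.0445 to 0.816 ± 0.118 CPM). Only 5 of the 16 genes had a mean of at least 5 CPM over the 12 libraries. Lama1 was at 260.7 ± 29.3 CPM in naive WT, and it lies in a segment of chromosome 17 that was higher in KO clone 2. Of 10 primitive streak and mesoderm markers, 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.194 with an estimated correlation). The list lost its call without EpiLC WT replicate 2 (0.057). Eomes, a T-box factor, rose by 1.01 ± 0.291 (7.76 ± 2.62 to 15.7 ± 2.99 CPM). That call ended without EpiLC WT replicate 1 (0.0572), EpiLC WT replicate 3 (0.106), EpiLC KO replicate 1 (0.113) or EpiLC KO replicate 3 (0.0999). Evx1, which also rose, stayed under 1 CPM in both groups.

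Of 17 p53 targets, 9 rose and 0 fell in EpiLC KO, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.14e-05; adjusted p = 0.322 with an estimated correlation). Mdm2 rose by 0.70 ± 0.0936, Btg2 by 1.27 ± 0.179, Plk2 by 1.49 ± 0.252 and Ccng1 by 0.77 ± 0.135. Of 14 germline genes, 4 rose and 5 adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.548 with an estimated correlation), including Asz1 (3.14 ± 0.654) and Taf7l (1.60 ± 0.324). The list lost its call without EpiLC WT replicate 1 (0.103), EpiLC KO replicate 1 (0.0509) or EpiLC KO replicate 3 (0.071). Of 23 imprinted genes, 6 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0345; adjusted p = 0.322 with an estimated correlation). Nnat rose by 1.59 ± 0.236, while Grb10 (-2.44 ± 0.339, 310.9 ± 106 to 57.44 ± 20.7 CPM) and Phlda2 (-2.19 ± 0.371) fell. The imprinted list lost its call without EpiLC WT replicate 1 (0.0769), EpiLC WT replicate 3 (0.0772), EpiLC KO replicate 1 (0.0733) or EpiLC KO replicate 3 (0.071). Of 8 neuroectoderm markers, 2 rose, with 3 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0345; adjusted p = 0.418 with an estimated correlation), including Neurod1 (2.18 ± 0.338). That call ended without EpiLC WT replicate 2 (0.126), EpiLC KO replicate 1 (0.0596) or EpiLC KO replicate 2 (0.0522). Of 9 markers of 2-cell-like cells, 2 rose, Usp17la and Usp17lc, and 3 adjusted over the list alone (camera adjusted p = 0.0345; adjusted p = 0.548 with an estimated correlation). That list lost its call without EpiLC WT replicate 1 (0.0769), EpiLC WT replicate 2 (0.149) or EpiLC KO replicate 2 (0.325). The calls of Usp17la and Usp17lc ended without EpiLC KO replicate 2 (0.166 and 0.122) or EpiLC WT replicate 1 (0.105 and 0.0671), 2 (0.0717 and 0.0569) or 3 (0.0543 and 0.0656), and that of Usp17la also without EpiLC KO replicate 1 (0.0546).

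Pluripotency genes did not separate the genotypes in EpiLCs as a list, and EpiLC WT replicate 2 stood apart from the other EpiLC WT libraries. Of 15 naive genes, 0 rose or fell (median -0.40, camera adjusted p = 0.829). Of 20 formative and primed genes, 1 rose, Etv1 (0.74 ± 0.205; 0 adjusted over the list alone; camera adjusted p = 0.272), a call that ended without EpiLC KO replicate 1 (0.0772), EpiLC KO replicate 3 (0.107), EpiLC WT replicate 2 (0.05) or EpiLC WT replicate 3 (0.109). Of 8 core genes, 0 passed (camera adjusted p = 0.47). Esrrb, a naive transcription factor, gave 214.9 CPM in EpiLC WT replicate 2 against 63.74 and 56.26 CPM in replicates 1 and 3, and Zfp42 gave 174.5 CPM against 38.08 and 35.02 CPM. Without EpiLC WT replicate 2, 5 of 15 naive genes rose in EpiLC KO and the list passed (median 0.593, camera adjusted p = 0.0244; adjusted p = 0.492 with an estimated correlation). The ATF4 list (19 of 26 fell, median -1.62) and the endoderm list (11 of 16 rose, median 2.71) then passed with the preset correlation but not with an estimated correlation (adjusted p of 0.393 and 0.208). Zfp42 was then higher in EpiLC KO (0.72, adjusted p = 0.0327), as was Tcl1 (0.99, adjusted p = 0.0373).

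**Figure D2:**
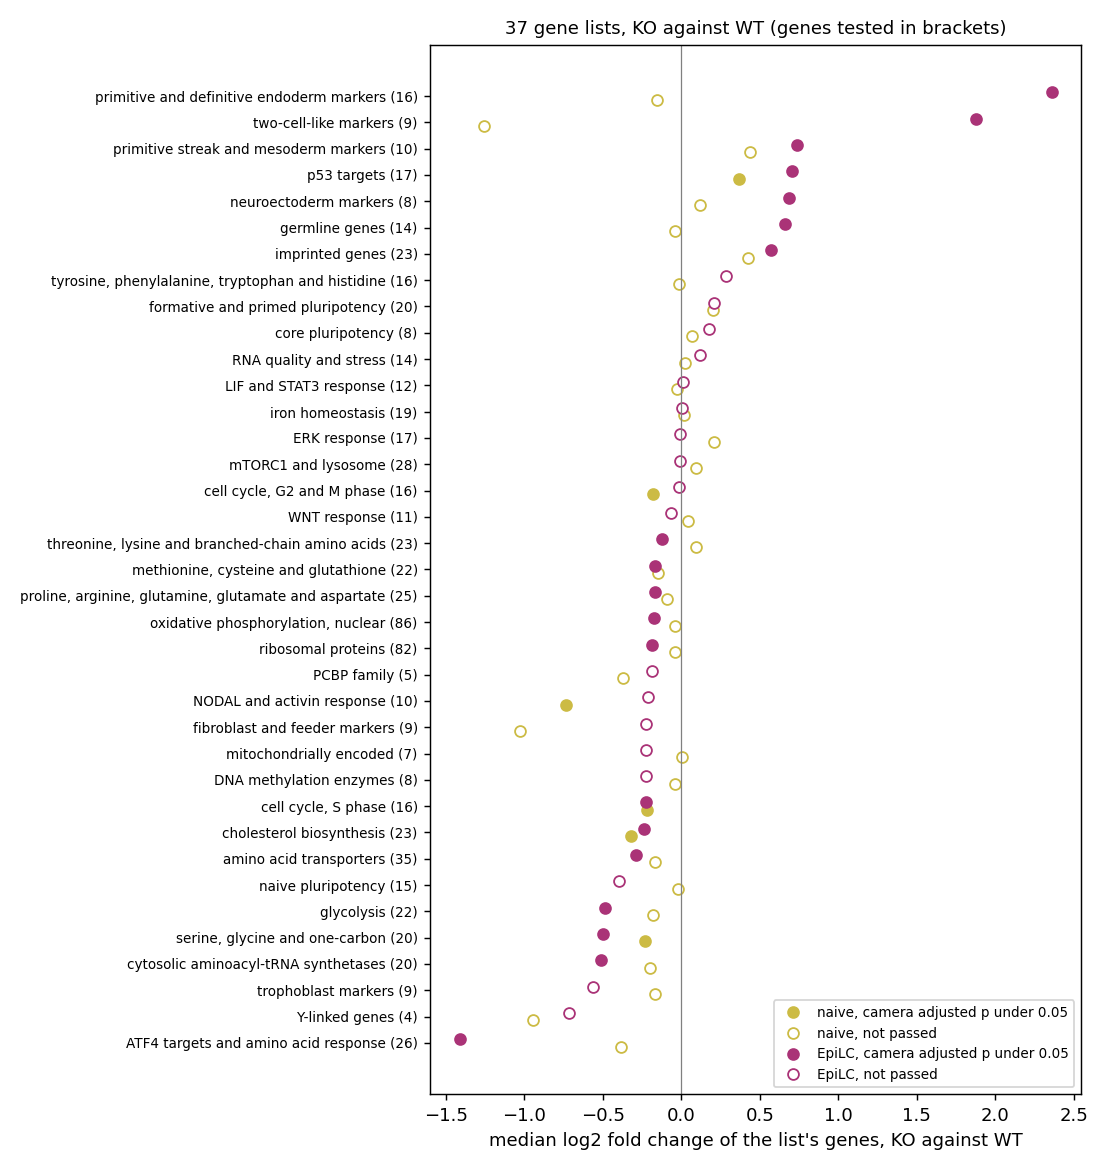
Median log2 fold change of KO against WT (horizontal axis) of each of the 37 gene lists (vertical axis, genes tested in brackets), in naive cells and in EpiLCs. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, 6 lists in naive cells and 19 in EpiLCs; with an estimated correlation 0 and 1 passed. The lowest EpiLC median is that of the ATF4 list (-1.41) and the highest that of the endoderm list (2.36).

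Across all genes, 2734 differed between EpiLC KO and EpiLC WT (1309 rose and 1425 fell), 1350 of them by at least 2-fold (867 rose and 483 fell). The count was 1754 without EpiLC WT replicate 3, 1375 without EpiLC KO replicate 1 and 1814 without EpiLC KO replicate 3. The log2 fold change correlated across genes with transcript GC content (Spearman -0.324), and 2507 genes passed with the GC trend of each library removed, an alternative chosen after seeing the data. These included 1964 of the 2734, or 71.8%. Of the genes called in both conditions, 413 rose in both (55.9 expected from independent draws), 369 fell in both (70.6 expected) and 16 had opposite signs. Got1, Gldc, Galk1, Foxh1, Magea2, Magea8 and Phlda2 were among those with the same sign. The naive and EpiLC libraries came from the same clones, so differences between clones count toward this overlap.

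The third comparison described the transition itself, in WT and in KO. In WT, the formative gene Fgf5, a growth factor gene, rose by 7.67 ± 0.232 (0.548 ± 0.106 to 111.2 ± 25.2 CPM, SD, n = 3), Pou3f1, a POU-domain factor, by 7.99 ± 0.297 and the DNA methyltransferase genes Dnmt3a and Dnmt3b by 6.29 ± 0.219 and 4.98 ± 0.31. The naive factors Klf4, Tfcp2l1, Nanog and Esrrb fell by 6.05 ± 0.429, 5.29 ± 0.334, 3.90 ± 0.321 and 2.92 ± 0.45. The highest fold changes were those of Crocc2 (8.49 ± 0.291), Vrtn (8.44 ± 0.32), Car4 (8.26 ± 0.276), Ccdc194 (8.11 ± 0.461) and Jph4 (8.07 ± 0.7). The lowest were those of Hoxc12 (-8.67 ± 0.48), Mal (-8.41 ± 0.514), Sp5 (-8.32 ± 0.659) and Cdx1 (-8.11 ± 0.489), both WNT targets, and Trpm1 (-7.78 ± 0.344). The lower group of Crocc2, Ccdc194 and Hoxc12 was near the level of 3 counts, and Jph4 lies in the part of chromosome 14 that was lower in WT clone 2.

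Of 20 formative and primed genes, 20 rose in WT, also 20 adjusted over the list alone (camera adjusted p = 9.88e-12; adjusted p = 0.0948 with an estimated correlation). The call of Foxd3 ended without EpiLC WT replicate 1 (adjusted p = 0.256), naive WT replicate 1 (0.168) or naive WT replicate 3 (0.181), and that of Cdh2 without EpiLC WT replicate 1 (0.0553). Of 15 naive genes, 13 fell and 0 rose, also 13 adjusted over the list alone (camera adjusted p = 6.9e-06; adjusted p = 0.487 with an estimated correlation). Nr0b1 (-0.71 ± 0.532) and Gbx2 (0.46 ± 0.385) did not pass, and Nr0b1 passed without EpiLC WT replicate 2 (-1.91, adjusted p = 0.000669). Of 12 genes of the LIF and STAT3 response, 10 fell and 11 adjusted over the list alone (camera adjusted p = 2.95e-05; adjusted p = 0.376 with an estimated correlation), for example Socs3 (-5.33 ± 0.182). Of 17 ERK response genes, 13 rose and 1 fell, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 4.35e-05; adjusted p = 0.0948 with an estimated correlation), for example Dusp4 (7.63 ± 0.327) and Spry4 (6.17 ± 0.269). Of 22 glycolysis genes, 16 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00158; adjusted p = 0.487 with an estimated correlation): the lactate transporter gene Slc16a3 rose by 6.59 ± 0.245 and Hk1 fell by 2.00 ± 0.134. Of 23 cholesterol genes, 15 rose and 3 fell, and 17 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.405 with an estimated correlation).

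In WT, 13 of 23 imprinted genes rose and 3 fell, and 14 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.376 with an estimated correlation). Of 16 S phase genes, 11 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0354; adjusted p = 0.772 with an estimated correlation), a call that ended without naive WT replicate 2 (0.0904), naive WT replicate 3 (0.0507), EpiLC WT replicate 1 (0.059) or EpiLC WT replicate 2 (0.0561). Of 28 mTORC1 and lysosome genes, 15 fell and 6 rose, the same counts adjusted over the list alone (camera adjusted p = 0.0354; adjusted p = 0.224 with an estimated correlation), a call that ended without EpiLC WT replicate 2 (0.0696) or with a block by clone (0.106). In KO, 20 of 20 formative genes rose (camera adjusted p = 2.98e-11; adjusted p = 0.132 with an estimated correlation) and 14 of 15 naive genes fell with 1 rising (camera adjusted p = 8.99e-06; adjusted p = 0.444 with an estimated correlation), the same counts adjusted over the list alone. The gene that rose, Gbx2 (1.04 ± 0.386), lost its call without EpiLC KO replicate 2 (0.202), naive KO replicate 2 (0.104) or naive KO replicate 3 (0.0667). Of 16 endoderm markers, 13 rose and 2 fell in KO, the same counts adjusted over the list alone (camera adjusted p = 0.00247; adjusted p = 0.444 with an estimated correlation), against 6 and 2 in WT (camera adjusted p = 0.5).

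In WT, 9553 genes changed between naive cells and EpiLCs (4780 rose and 4773 fell), and in KO, 10010 (4914 rose and 5096 fell). With a block by clone the counts were 9154 and 10808. Of the genes called in WT, 7800 were called with the same sign in KO, 24 with the opposite sign and 1729 in WT alone, while 2186 were called in KO alone. The log2 fold change in KO was a median 0.945 of that in WT over the genes called in WT (95% bootstrap interval 0.936 to 0.955) and 1.11 over the genes called in KO. Genes are not independent replicates, and genes picked in 1 genotype favour it. The ratio was 0.874 without EpiLC WT replicate 2.

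The transition score, the mean log2 CPM of the formative list minus that of the naive list, was -5.58 ± 0.128 in naive WT, -5.42 ± 0.0533 in naive KO, 2.38 ± 1.30 in EpiLC WT and 2.68 ± 0.392 in EpiLC KO (SD, n = 3). KO and WT differed by 0.159 in naive cells (2-sided exact permutation p = 0.2) and by 0.297 in EpiLCs (exact p = 0.9), the latter within the spread between replicates. EpiLC WT replicate 2 gave 0.897 against 3.28 and 2.97 in replicates 1 and 3, and without it the EpiLC difference was -0.445. That difference was 0.748 without EpiLC WT replicate 1, 0.589 without EpiLC WT replicate 3, 0.135 without EpiLC KO replicate 1 and 0.515 without EpiLC KO replicate 3, and the naive difference was 0.092 without naive WT replicate 3. Between culture conditions the score differed by 7.97 in WT and 8.10 in KO (exact p = 0.1 for each, the smallest that 3 against 3 libraries allow). By clone, the score rose by 8.85, 6.36 and 8.68 in WT and by 8.40, 8.18 and 7.73 in KO.

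**Figure D3:**
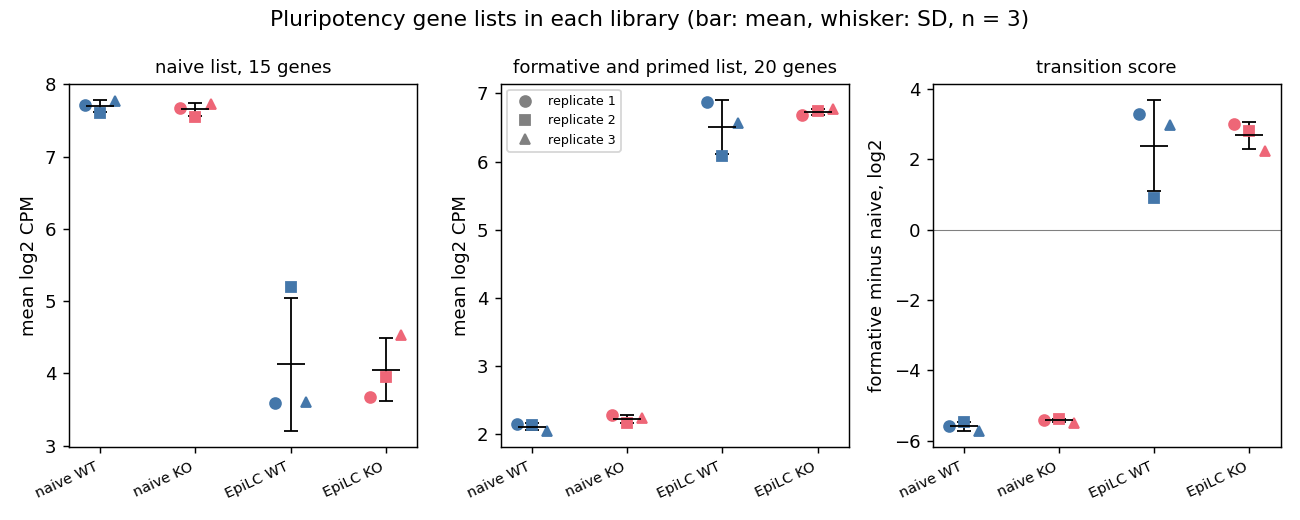
Mean log2 CPM of the 15 naive and the 20 formative and primed genes and the transition score (vertical axes) in each of the 12 libraries, in 4 groups along the horizontal axes, with the mean (bar) and SD (whisker, n = 3). Symbols mark the replicate number. EpiLC WT replicate 2 has a naive list mean of 5.19, above the other EpiLC libraries (3.59 to 4.53).

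The interaction asked whether the knockout changed the response to EpiLC medium. Amot, which encodes angiomotin, an actin-binding regulator of the Hippo pathway, was lower in KO than in WT in naive cells (1.94 to 0.632 CPM) and higher in EpiLCs (8.62 to 42.2 CPM), an interaction of 3.92 ± 0.427 (edgeR adjusted p = 0.0115, n = 3 per group). Calb2 differed by genotype in naive cells (-4.27) but not detectably in EpiLCs (2.22 and 2.02 CPM), an interaction of 4.13 ± 0.509 (adjusted p = 0.0143). Aff1, which encodes a subunit of the super elongation complex, had an interaction of -1.18 ± 0.14 (adjusted p = 0.0143): it was at 407 and 423 CPM in naive WT and KO, and at 226.5 and 103.9 CPM in EpiLC WT and KO. Across all genes, 69 passed (47 higher and 22 lower in the KO response), 228 with a block by clone and 516 by DESeq2. At a stricter adjusted p of 0.01 the edgeR fit called 0, while 2236 genes had an unadjusted p under 0.05. The count ranged from 3 without EpiLC KO replicate 1 to 149 without EpiLC WT replicate 2. It was also 28, 10 and 20 without naive WT replicate 1, naive WT replicate 3 and EpiLC WT replicate 1, 15 and 16 without naive KO replicates 1 and 2, 121 without naive KO replicate 3, 16 without EpiLC WT replicate 3, and 7 and 23 without EpiLC KO replicates 2 and 3.

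Chromosome sets were compared because cultured clones can gain or lose chromosomes. Genes of chromosome 14 were higher in KO than in WT in naive cells (355 genes with a mean of at least 5 CPM, median 0.186, camera adjusted p = 0.000211, 18 rose and 7 fell) and in EpiLCs (median 0.172, camera adjusted p = 0.00023, 28 rose and 10 fell). The median log2 ratio of chromosome 14 to the WT mean was -0.290 in naive WT replicate 2 and -0.293 in EpiLC WT replicate 2, against 0.12 to 0.274 in the other 10 libraries. Without replicate 2 of WT in both conditions, an alternative chosen after seeing the data, the medians were 0.0264 (camera adjusted p = 0.457) and 0.0466 (0.148). Genes of chromosome 7 were lower in EpiLC KO (825 genes, median -0.154, camera adjusted p = 0.0239, 160 fell and 44 rose), a call that ended when genes with a mean of at least 1 CPM were included. In naive cells chromosome 7 did not pass (median -0.102, camera adjusted p = 0.0943). The chromosome 7 medians of the EpiLC libraries ranked as the Spearman correlation of each library's deviation with transcript GC content. They went from 0.0757 in EpiLC WT replicate 1 (Spearman 0.455) to -0.214 in EpiLC KO replicate 1 (-0.369). Chromosomes were not tested with the GC trend removed, so the call does not separate chromosome 7 from GC content.

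**Figure D4:**
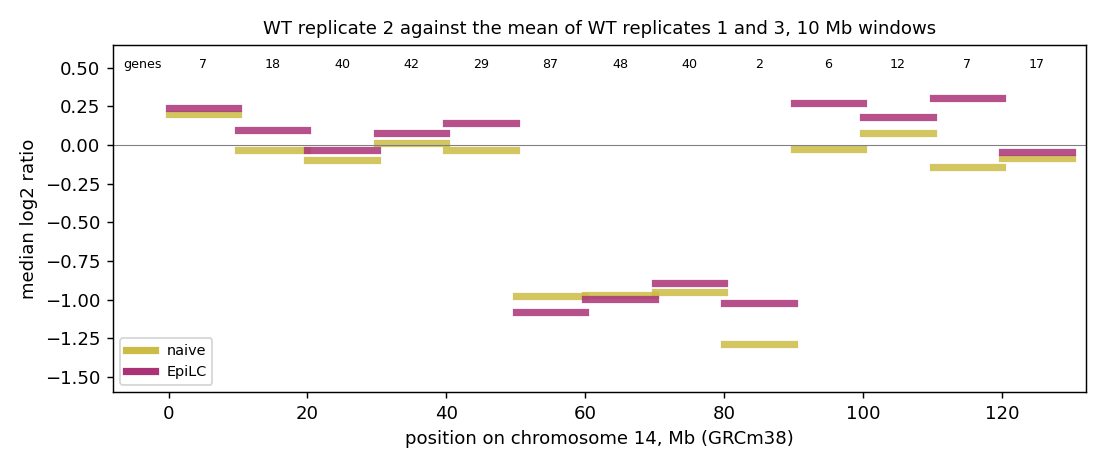
Median log2 ratio (vertical axis) of WT replicate 2 to the mean of WT replicates 1 and 3 in windows of 10 Mb along chromosome 14 (horizontal axis, Mb, GRCm38), in naive cells and EpiLCs. The numbers at the top give the genes per window. The windows from 50 to 80 Mb lie between -0.89 and -1.08.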

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

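The tests of the endoderm and ATF4 patterns were chosen after the patterns were seen, and before the value of each test was computed. The list means per library, which fix the outcome of omitting EpiLC WT replicate 2, had been computed by then. The split of clones for the interaction was chosen after its values were seen. The results here were singled out because the effect of the knockout differed between naive cells and EpiLCs by a test of the difference itself, the interaction term of the edgeR fit. Across all genes 69 passed.

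Of the genes named by the rule, the knockout effect was higher in EpiLCs than in naive cells for 11. These were Foxa2 (interaction 4.93, adjusted p = 0.0482), Calb2 (4.13, 0.0143), Amot (3.92, 0.0115), Sox17 (3.86, 0.0478), Tbx15 (3.66, 0.0342), Id2 (3.66, 0.0498), Gata4 (3.62, 0.0412), Lbh (3.51, 0.0332), Dzip1l (3.10, 0.038), Ggct (1.23, 0.0482) and Ccne1 (0.638, 0.0425). It was lower in EpiLCs for 9: Etv5 (-0.591, 0.0399), Amt (-1.08, 0.0165), Asns (-1.09, 0.0165), Aff1 (-1.18, 0.0143), Cldn4 (-1.43, 0.0342), Scarf1 (-1.68, 0.045), Dusp1 (-1.94, 0.0165), Cotl1 (-2.34, 0.0412) and Epha7 (-2.99, 0.0342). Foxa2, Sox17 and Gata4 are endoderm transcription factors. The interaction of Foxa2 was larger than its rise in EpiLC KO, so part of it comes from a lower level in naive KO. In EpiLC WT Foxa2 lay near the level of 3 counts. Tbx15 fell from 36.4 to 5.83 CPM in naive KO and lay at 1.13 and 2.28 CPM in EpiLC WT and KO. Its interaction therefore joins the naive fall with a higher mean in EpiLC KO, while that of Calb2 reflects the naive fall. Calb2, Amot and Aff1 passed without each of the 12 libraries in turn. The other 17 lost their calls without EpiLC KO replicate 1 (adjusted p from 0.0633 to 0.145), and each without at least 1 further library. These fits had no block by clone, with which 228 genes passed, and each omission kept the other library of the clone. Gata4 lies in the part of chromosome 14 that was lower in WT clone 2, Lbh in a part of chromosome 17 that was higher in KO clone 2, and Dusp1 overlaps Ergic1.

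Of the 37 lists, 11 passed for the interaction with the preset correlation, and 0 with an estimated correlation. ATF4 targets had a median interaction of -1.02 (camera adjusted p = 3.4e-09; adjusted p = 0.461 with an estimated correlation), glycolysis -0.397 (9.41e-05; 0.461), cytosolic aminoacyl-tRNA synthetases -0.354 (0.000473; 0.461), endoderm markers 1.9 (1.85e-08; 0.461) and 2-cell-like markers 3.98 (0.00139; 0.461). These 5 passed without each library in turn. Of the 9 markers of 2-cell-like cells, only 1 had a mean of at least 5 CPM over the 12 libraries. Their median KO against WT was -1.26 in naive cells and 1.88 in EpiLCs, so part of their interaction comes from naive cells. The EpiLC median was 0.328 without EpiLC KO replicate 2 (camera adjusted p = 0.325). Over all genes, 1 of 26 ATF4 targets, 0 of 22 glycolysis genes, 0 of 20 synthetases, 3 of 16 endoderm markers and 0 of 9 markers of 2-cell-like cells passed in edgeR. Adjusted over the list alone, 9 ATF4 targets, 9 glycolysis genes, 0 synthetases, 9 endoderm markers and 4 markers of 2-cell-like cells passed in the direction of their list, and 1 endoderm marker in the opposite direction. Threonine, lysine and branched-chain amino acids (-0.275, 0.00692, and 0.461 with an estimated correlation) lost its call without EpiLC WT replicate 2 (0.0788, median -0.17). Ribosomal proteins (-0.151, 0.00114, and 0.733) lost theirs without naive WT replicate 3 (0.082, median -0.0608). Nuclear oxidative phosphorylation (-0.119, 0.00791, and 0.733) lost its call without naive WT replicate 3 (0.175) or EpiLC KO replicate 1 (0.366), with a median of -0.0465 in each case. The NODAL and activin response (0.397, 0.0324; 0.461) lost its call without naive WT replicate 1 (0.0754), naive KO replicate 2 (0.0637), EpiLC WT replicate 2 (0.148), EpiLC WT replicate 3 (0.0635) or EpiLC KO replicate 3 (0.158). G2 and M phase (0.171, 0.035; 0.495) lost its call without naive WT replicate 1 (0.113), naive KO replicate 1 (0.0855), EpiLC WT replicate 3 (0.159), EpiLC KO replicate 2 (0.0548) or EpiLC KO replicate 3 (0.138). Primitive streak and mesoderm markers (0.646, 0.0345; 0.461) lost its call without naive WT replicate 2 (0.0814), naive WT replicate 3 (0.0975), any naive KO library (0.0707, 0.092 and 0.0627), EpiLC WT replicate 2 (0.147) or EpiLC KO replicate 3 (0.0821), and with a block by clone (0.084).

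Naive and EpiLC libraries of the same number were taken to come from the same clone, so the 6 clones allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the real split (69) passed for the interaction in 1 of 10, the real one, and the highest other split gave 0. Relabelling genotype separately in each condition breaks the clones apart. In 100 such relabellings, 2 gave at least as many genes, the real one included, and the highest other gave 341. The 341 came from taking naive WT replicate 1 and naive KO replicates 1 and 3 as WT while the EpiLC labels stayed as they were, so that the EpiLC effect of genotype entered its contrast.

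Endoderm markers were higher in KO EpiLCs. The mean log2 CPM of the 16 genes was 1.82 ± 0.279 higher in KO than in WT, and 2.08 ± 0.128 higher without EpiLC WT replicate 2, the library that kept naive transcripts. That library had the WT mean nearest KO (1.463, against 0.7574 and 0.6625 in replicates 1 and 3). Its omission could only enlarge the difference, so these values show only that this library did not create it. Of 10000 random lists matched on mean expression over all 12 libraries, the highest median was 1.15 against 2.36 for the list (percentile 100). This argues against a rise of genes of that mean level as a whole. The match included naive cells, so it does not decide whether genes low in EpiLCs rose as a whole. The KO EpiLC libraries had a count for 26772 to 27834 genes, and the WT EpiLC libraries for 24375 to 25190. Endoderm-like cells within the KO cultures, or a rise in most cells, may explain the pattern, and bulk RNA does not separate these. Differences between clones stay open with 3 clones per genotype.

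ATF4 targets were lower in KO EpiLCs. The mean log2 CPM of the 26 genes was -1.43 ± 0.183 in KO relative to WT, and -1.59 ± 0.0985 without EpiLC WT replicate 2. That library again had the WT mean nearest KO (5.563, against 5.992 and 6.084 in replicates 1 and 3). The values therefore show only that it did not create the difference. The mean log2 fold change was -1.47 before and -1.47 after the trend on GC content was removed, which argues against GC content as the cause. A weaker amino acid or integrated stress response in KO EpiLCs may explain the pattern, as may a different state of the medium at harvest in the 2 genotypes, and neither was tested. No protein or metabolite data were at hand to separate them.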

How the results depend on the processing

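Of the alternatives given here, the removal of the GC trend and the estimated correlation with EpiLC WT replicate 2 omitted were chosen after seeing the data. For KO against WT in naive cells (1673 genes) DESeq2 called 2516, a mean of at least 5 CPM left 888, an adjusted p of 0.01 left 584, a fold change of at least 2 left 1049, and a block by replicate number, which does not pair WT with KO, gave 887. For EpiLCs (2734 genes) these were 3547 by DESeq2, 1803, 998, 1350 and 882. The compared libraries alone, where each clone enters once and fewer residual degrees of freedom remain, gave 1437 genes in naive cells and 1975 in EpiLCs. For EpiLC against naive in WT and KO a mean of at least 5 CPM left 6095 and 6202 genes, and a fold change of at least 2 left 5781 and 6122. For the interaction (69 genes) DESeq2 called 516, no filter on low counts gave 564, a mean of at least 5 CPM 40, an adjusted p of 0.01 0, and a block by clone 228. Stricter thresholds and filters lower a count by construction. The DESeq2 test made more false calls than edgeR on data simulated with the edgeR dispersions for the KO against WT contrasts. It was not run on simulated data for the interaction. On simulated data the block by replicate number made 5.95% false calls in naive cells and 13.2% in EpiLCs, and the block by clone 8.7% for the interaction. Those data held no differences between clones, so they do not show which interaction fit is sounder here. The cause of the higher interaction count without a filter was not tested.

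Omitting each library in turn gave 678 to 1744 genes for KO against WT in naive cells, 1375 to 3117 in EpiLCs and 3 to 149 for the interaction. Fewer libraries give less power by construction. The cause of the counts above the full ones was not tested. In EpiLC KO against EpiLC WT, Zfp42 had a log2 fold change of 0.7181 and Tcl1 of 0.9922 without EpiLC WT replicate 2, both past the threshold. Without any 1 of the other libraries they were negative and not past it, the lowest being -0.821 (Zfp42, without EpiLC WT replicate 3) and -0.7462 (Tcl1, without EpiLC KO replicate 3).

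With an estimated correlation camera called 0 lists in naive cells, 1 in EpiLCs, 0 for EpiLC against naive in WT, 0 in KO and 0 for the interaction, and 0 in EpiLCs when EpiLC WT replicate 2 was also omitted. Fry called 12, 17, 22, 27 and 1 in the same order. The estimated correlation widens the error of lists whose genes vary together between libraries. The share of the WT transition seen in KO (0.945) was 1.11 over the genes called in KO, and 0.874 to 0.966 with each library omitted. The chromosome sets called in EpiLC KO against EpiLC WT went from 2 to 1 when genes of at least 1 CPM were included. With the GC trend removed 1793, 2507, 9751, 10280 and 78 genes were called in the 5 contrasts.

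Of the alternative values of the counts and summary values, 145 kept their side of the threshold, stayed within 1.5 times or, where no test applied, moved by less than the spread between replicates, 37 were weaker, 9 stronger and 5 moved. The 145 include the EpiLC difference in transition score, which turned from 0.297 to -0.445 without EpiLC WT replicate 2, within that spread. The spread includes that library, whose score was 0.8968 against 3.284 and 2.965 in EpiLC WT replicates 1 and 3 (SD 1.30 in EpiLC WT, 0.392 in EpiLC KO). The label therefore does not show that the sign of this difference is stable. For the gene lists 507 were the same and 148 weaker, and for the named genes 11476 were the same, 625 weaker, 343 stronger and 2 reversed. Depth limits the genes of few counts: a count of 3 came to 0.0689 to 0.112 CPM.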

Other observations

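The tests of chromosome 14 without WT clone 2, the scan of windows and the removal of the GC trend were chosen after the results they concern were seen. Magea4 and Magea8 on the X chromosome, of a family usually limited to the germline, rose in KO in both conditions: Magea8 from 2.51 to 38.7 CPM in naive cells and from 1.06 to 42.8 CPM in EpiLCs, and Magea4 from 4.29 to 41.6 CPM in EpiLCs. Rhox5, another X-linked germline gene, rose in naive cells (2.47 ± 0.412, from 50.9 to 281.2 CPM) and did not pass in EpiLCs (-0.04, adjusted p = 0.96). Of 14 germline genes 3 rose in naive cells (camera adjusted p = 0.53). Among imprinted genes Phlda2 fell in both conditions (-2.70 and -2.19) and Mirg rose in both (0.88 and 0.58), while 2 rose and 2 fell in naive cells (camera adjusted p = 0.19). Of 8 DNA methylation enzymes 0 passed in either condition (camera adjusted p of 0.92 and 0.333). By fry the list was lower in EpiLC KO (mean log2 fold change -0.22, adjusted p = 0.0169). Dnmt1 passed in EpiLCs without EpiLC WT replicate 2 (-0.311, edgeR adjusted p = 0.0271).

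Y-linked genes varied between KO clones of this male line, and not in the same way for each gene. Eif2s3y gave 118.2, 127.8 and 123.8 CPM in naive WT and 43.0, 14.04 and 79.3 CPM in naive KO, and 58.6, 97.3 and 79.0 CPM in EpiLC WT and 24.2, 7.00 and 61.8 CPM in EpiLC KO. Kdm5d gave 1.92, 4.71 and 2.76 CPM in naive WT and 12.2, 3.06 and 21.8 CPM in naive KO. The mean log2 CPM of the list in naive cells was 4.79 to 5.13 in WT, and 4.50, 2.94 and 5.48 in KO clones 1, 2 and 3, so KO clones 1 and 2 lay below and KO clone 3 above the WT libraries. The list of 4 Y-linked genes did not pass (camera adjusted p of 0.508 in naive cells and 0.354 in EpiLCs), with 0 genes called.

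Other lists did not pass by camera in either KO against WT comparison. By fry, the PCBP family passed in naive cells (adjusted p = 0.0117) and in EpiLCs (0.00651). That list of 5 genes includes the targeted gene Pcbp1 and was not tested without it, so this does not show a change of the other members. In naive cells fry also passed the ERK response (0.0252), mTORC1 and lysosome (0.0237) and tyrosine, phenylalanine, tryptophan and histidine (0.0236). The ERK response in EpiLCs went both ways, from -1.5 to 1.27 (adjusted p = 1.56e-10 by fry for a mixed change). In naive cells and in EpiLCs, camera gave adjusted p of 0.132 and 0.856 for the ERK response (3 of 17 rose, then 1 rose and 3 fell; Dusp6 rose by 1.01 in naive cells and Spry2 by 1.27 in EpiLCs, Spry2 lying in a part of chromosome 14 that was higher in KO clones 1 and 2), 0.967 and 0.829 for the WNT response (0 of 11), and 0.919 and 0.919 for the LIF and STAT3 response (0 of 12, then 1 rose and 1 fell). It gave 0.31 and 0.836 for mTORC1 and lysosome (1 of 28 rose, then 2 rose and 1 fell), 0.629 and 0.272 for mitochondrially encoded genes (0 of 7), 0.528 and 0.829 for iron homeostasis (1 of 19 fell, then 1 rose and 1 fell), and 0.0729 and 0.0894 for the PCBP family (2 of 5 fell in each, Pcbp1 and Pcbp4). It gave 0.439 and 0.617 for tyrosine, phenylalanine, tryptophan and histidine (3 of 16 rose, then 2 rose and 1 fell; Ido2 rose by 1.94 in naive cells), 0.528 and 0.829 for trophoblast markers (2 of 9 fell, then 1), 0.409 and 0.713 for fibroblast and feeder markers (1 of 9 rose and 2 fell, then 0), and 0.551 and 0.513 for RNA quality and stress (3 of 14 fell, then 2 rose and 1 fell).

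Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits, the real one, for KO against WT in naive cells (1673; highest other 0) and in EpiLCs (2734; highest other 0), and for EpiLC against naive in WT (9553; highest other 0) and in KO (10010; highest other 1). The real split of the clones gave 782 genes changed the same way in both conditions, and the highest other split gave 0. The log2 fold changes in the 2 conditions correlated at 0.503 across genes in the real split and at 0.156 to 0.308 in the other 9. Part of the genotype effect stays in those 9, since their sides hold unequal numbers of WT and KO clones. They therefore do not show by themselves differences apart from genotype. Deviations from the group mean, which leave genotype out, correlated between the libraries of a clone (0.299 to 0.377 in WT, 0.243 to 0.387 in KO). In EpiLCs a KO and a WT library, of different clones, reached 0.449.

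Transcript GC content went with genotype. Across genes, the Spearman correlation of a library's deviation with GC content was 0.018 to 0.455 in WT and -0.369 to -0.0355 in KO. Genes that fell in KO had a median GC content of 53.8% in naive cells and 54.1% in EpiLCs, and genes that rose 46.8% and 46.2%, against 49.6% for the genes tested. The data do not separate a preparation effect from a biological one here, and no test of either was run.

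Chromosome 14 genes were higher in KO than in WT as a set. Without WT clone 2 the median in naive cells went from 0.186 to 0.0264, which is consistent with lower chromosome 14 transcripts in that clone as the source. A lower dose of the whole chromosome was argued against, since 17.6% of its 119 genes nearest the start (up to 46771669) were lowest in WT clone 2 in both conditions, against 82.2% of the next 118 genes and 24.5% on the highest other autosome (11.1% by chance). A loss of part of the chromosome in that clone may explain it; DNA was not measured, and no biological explanation was tested. Without WT clone 2 in both conditions 1761 genes were called in naive cells and 3423 in EpiLCs.

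A scan of 245 windows of 10 Mb in the 6 clones found 11 in which the median log2 ratio was beyond 0.4 in the same direction in both conditions. They were the windows from 50 to 80 Mb of chromosome 14 in WT clone 2, the windows starting at 100 and 120 Mb of chromosome 14 in KO clones 1 and 2 (0.421 to 0.686), and on chromosome 17 of KO clone 2 those starting at 40, 60 and 70 Mb (0.444 to 0.572) and at 80 Mb (-0.852 and -0.824). Lama1, Lbh, Spry2, Pcca, Zic2 and Zic5 lie in the KO windows, and Jph4, Sall2, Slc7a7 and Tdh in those of WT clone 2, where 3 of 175 genes rose and 2 fell in naive KO and 5 rose and 1 fell in EpiLC KO. In the KO windows the genes that rose were, at 100 Mb of chromosome 14, 1 of 12 in naive KO and 4 in EpiLC KO, and at 120 Mb 4 of 17 and 3. On chromosome 17 these were 3 of 63 and 4 at 40 Mb, 0 of 21 and 5 at 60 Mb, 1 of 39 and 2 at 70 Mb, and 0 of 36 and 3 at 80 Mb. Genes also fell there: 2 in EpiLC KO at 40 Mb, 2 in naive KO at 70 Mb, and 1 in EpiLC KO at 80 Mb. Smaller shifts escape this limit: the median log2 ratio of the 360 chromosome 19 genes to the WT mean was 0.261 in naive and 0.262 in EpiLC KO clone 3, against -0.158 to -0.0666 in KO clones 1 and 2. Got1 and Gldc, which fell in KO, lie on chromosome 19.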
